A study of Mus musculus with 22 samples.

How the data were processed

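The series holds bulk RNA sequencing of the mouse retina and choroid, dissected together, after laser burns that open the barrier under the retina and start choroidal neovascularisation (CNV), the growth of choroidal vessels into the retina. The wild-type strain (C57BL/6J) gave 16 libraries, 4 each from controls without CNV and from eyes at day 3, day 7 and day 14 after the laser. A second set gave 6 libraries at day 3 after the laser, 3 from Rag2 knockout mice, which make no T or B cells, and 3 from Rag2 knockout mice that also lack the common gamma chain (written here as Rag2 gc KO), the receptor subunit NK cells need to develop. RNA was extracted with TRIzol and the libraries were made by Novogene, per the labels' protocols.

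The authors deposited 1 table per strain set, each with 54532 genes and 1 column of raw counts per library, counted with featureCounts 1.5.0-p3 on the mm10 genome build, per the submitters' processing notes. The aligner, the annotation release and the strand setting are not given in the sources used here. Gene IDs and symbols were taken from the deposited tables. Of the gene models, 98.26% had the same start and end as in GENCODE M21 on the same build, and coordinates are as deposited, on mm10. The authors also deposited FPKM values. In each library these equal the count divided by gene length times 1 constant. They add nothing to the counts and were used for that check only. The wild-type table also holds the authors' own comparisons with control. Per the file headers these give a mean signal per group, which the values show to be counts scaled by 1 factor per library and averaged over the 4 replicates. They also give the authors' log2 fold change, p-value and adjusted p-value. The tool behind that comparison is not given either, and its values only served to compare numbers of changed genes.

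The deposited counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr at its defaults (a minimum count of 10 and a minimum total count of 15), which left 18657 genes in the wild-type table and 18923 in the Rag2 table. Libraries were scaled by TMM factors. The quasi-likelihood model of edgeR was fitted with robust estimation and group means only, over all 16 wild-type libraries together for the wild-type comparisons and over the 6 Rag2 libraries for the other. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Counts-per-million values (CPM) are means over the replicates with their SD, scaled by the same factors, and log2 fold changes carry the SE of the model. The 2 tables were normalised and fitted separately, and no test was made across them, since strain and table cannot be told apart.

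Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The 37 lists, with 614 symbols of which 612 matched, covered NK cells, neutrophils, neutrophil recruitment, T cells, B cells, other innate lymphoid cells, monocytes and macrophages, microglia, dendritic cells and mast cells. They also covered endothelial cells, angiogenic factors, extracellular matrix and fibrosis, complement, chemokines, type I interferon, interferon gamma and antigen presentation, and common gamma chain receptors. Retinal lists were Muller glia, reactive gliosis, rod photoreceptors, cone photoreceptors, bipolar cells, amacrine and horizontal cells, retinal ganglion cells, retinal pigment epithelium and melanogenesis. The rest were pericytes and smooth muscle, oligodendrocytes, lens, cornea and conjunctiva, skeletal muscle, erythrocytes, proliferation, hypoxia and glycolysis, immediate early genes and sex-linked genes. A list score is the mean log2 CPM of its tested members in a library, compared between groups with a two-sided exact permutation test, whose smallest p is 0.0286 for 4 against 4 and 0.1 for 3 against 3.

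The lists, the tests, the alternatives of the first kind below and the rule for named genes were chosen before the data were examined. The rule takes Il2rg and Rag2 in the Rag2 comparison. In each comparison it takes the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 CPM and no overlap between the groups' CPM values. It adds the 3 members of each list with the smallest p, and any member of the NK cell list. The text picks from these. Some list members named in the text fall outside the rule, and these were chosen after their values were seen. Some genes counted in the text are not reported here by name.

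Control replicate 4 has a title that says no CNV and a treatment tag that says laser. It was kept in the control group, and every comparison with control was also made without it. The labels do not say that each library came from a separate animal, and the treatment protocol speaks of a range of adult mice, so the p-values measure the spread between libraries only.

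Total counts were 15033983 to 16848254 per wild-type library and 27227847 to 30315086 per Rag2 library. The reads carry no molecular identifiers and copies made by PCR are not independent, so floors and intervals cover counting error only. Where a group had 0 counts, a floor of 3 counts over the group was used. The replicates of a group differed by more than counting error in every pair, with a lowest chi-square per degree of freedom of 10.14.

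The fits were tested on simulated counts drawn from the libraries' own means and spreads, with 200 of 18382 to 18635 genes changed by 2-fold or 4-fold. At day 3 edgeR recovered 41% of the 2-fold and 83% of the 4-fold changes, and 5.34% of its calls were false. At day 7 these were 47%, 90% and 2.14%, and 50%, 85% and 4.26% at day 14. For day 7 against day 3 they were 43%, 89% and 2.22%, and 58%, 83% and 1.4% for day 14 against day 7. For the Rag2 comparison edgeR recovered 69% and 94%, but 14.7% of its calls were false, and it called 6 genes where nothing was changed. DESeq2 had 11.3% to 26.7% false calls over the 6 comparisons. In each comparison camera and fry found the shifted list. Camera called 0 unchanged lists, and fry 1 for day 7 against day 3 and 2 for day 14 against day 7. Means and spreads hold no correlation between genes, so lists whose members move together were not tested.

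Alternatives fixed in advance were DESeq2 1.42.0 and limma voom as other tools, the size factors of DESeq2 or library totals as other scalings, no filter or a filter of 1 CPM, protein-coding genes only, only the groups compared in the fit, the replicate number as a block, an adjusted p under 0.01, a log2 fold change of at least 1, and each library left out in turn. Alternatives chosen after seeing the data left out day 3 replicate 3, day 7 replicate 2 and day 14 replicate 1 together, left day 14 replicate 1 out of the shared spread, or took the lens score and the cornea and conjunctiva score of each library as covariates. Exact permutation of list scores and summed counts of NK cell genes were also added then. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.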

Results

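Bulk RNA sequencing of retina and choroid covered 22 libraries in 6 groups. The wild type had 4 controls without CNV and 4 libraries each at day 3, day 7 and day 14 after the laser. Rag2 KO and Rag2 gc KO had 3 each, all at day 3. The series asks how genes of natural killer (NK) cells behave over the time course, and the Rag2 pair asks how NK cells protect against CNV.

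The 16 wild-type libraries differed in their content of lens and ocular surface transcripts. The lens list took 0.51% ± 0.739 of all counts in control (SD, n = 4), 4.83% ± 1.61 at day 3, 2.09% ± 1.88 at day 7 and 4.71% ± 6.68 at day 14. The cornea and conjunctiva list took 0.487% ± 0.229, 1.55% ± 1.25, 1.63% ± 1.13 and 1.07% ± 0.555 in the same order (SD, n = 4). No gene of these 2 lists is in another list. Day 14 replicate 1 stood farthest apart, with 14.6% of its counts in the lens list (95% Wilson interval 14.6% to 14.64%) and 1.57% in the rod photoreceptor list (1.568% to 1.58%). In the Rag2 set, which was counted and normalised separately, the lens list took 0.56% ± 0.372 in Rag2 KO and 0.536% ± 0.495 in Rag2 gc KO (SD, n = 3), and the cornea and conjunctiva list 0.00178% ± 0.000333 and 0.00186% ± 0.000511 (SD, n = 3). Mitochondrial genes took 3.01% ± 0.2 of all counts in control, 3.61% ± 0.426 at day 3, 4.06% ± 0.317 at day 7 and 4.08% ± 0.189 at day 14 (SD, n = 4), with every day 7 and day 14 library above every control, and whether this bears on the changes below was not tested. Control replicate 4, whose treatment tag says laser CNV, had a reactive gliosis score of 3.909 (mean log2 CPM), beside 4.084 to 4.133 in the other controls and 4.603 to 6.367 in the 12 CNV libraries.

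**Figure D1:**
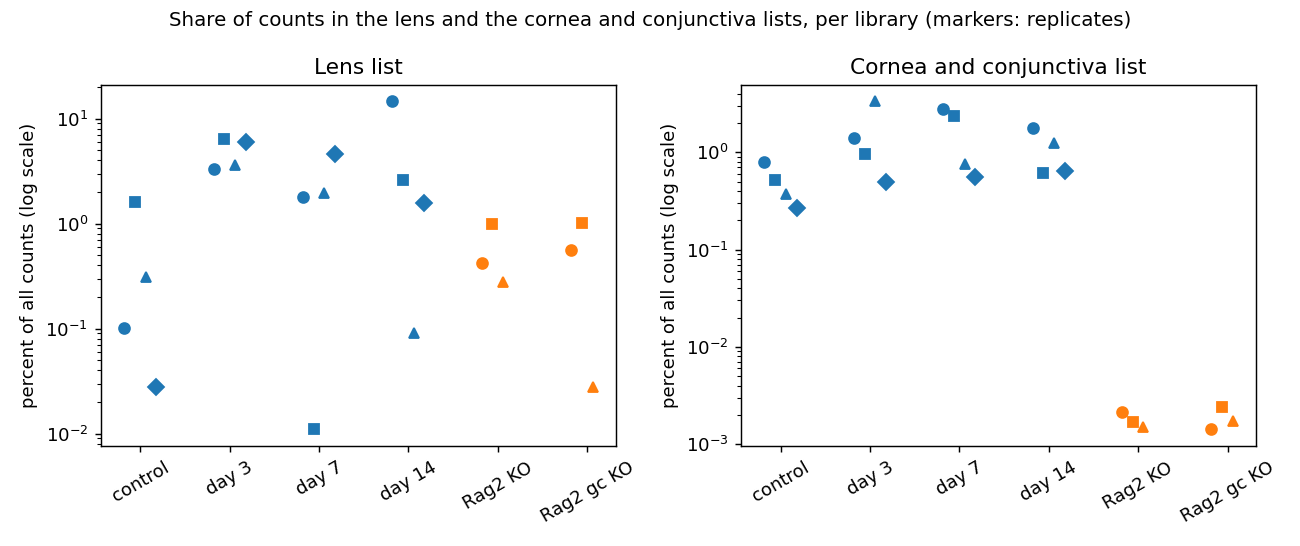
The share of all counts in the lens list and in the cornea and conjunctiva list is drawn per library on a log scale, in percent, with wild-type libraries in blue and Rag2 libraries in orange. The lens share reached 14.6% in day 14 replicate 1 (wild-type and Rag2 sets were normalised separately).

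At day 3 after the laser, many genes of gliosis, inflammation and cell division were higher than in control. Edn2, a vasoactive peptide that stressed photoreceptors release (ENSMUSG00000028635, chromosome 4, 120161206 to 120167360 on mm10), rose from 5.02 ± 0.828 to 128 ± 48.5 CPM (SD, n = 4), a log2 fold change of 4.66 ± 0.37 (SE, edgeR adjusted p = 4.32e-05). By camera the macrophage, microglia, complement and matrix lists rose with it (16 of 22, 7 of 12, 12 of 17 and 8 of 25 genes called), and the ganglion cell and pigment epithelium lists fell (3 of 13 and 6 of 16). None of these 6 lists passed with an estimated correlation, and the 2 lower ones did not with lens and cornea scores as covariates. By fry 11 and by exact permutation of list scores 20 of the 25 lists called at day 3 kept their call. In all, edgeR called 2749 genes, 1300 higher and 1449 lower, of which 761 and 401 changed at least 2-fold. With scaling by library totals it called 2409, with 1405 higher and 1004 lower.

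Glial and early stress genes stood out at day 3. Beside each list's median log2 fold change stand its adjusted p by camera (camera p) and with an estimated correlation (estimated-correlation p). List-wise counts are of genes that pass when p is adjusted over the list alone. Of 19 measured reactive gliosis genes, 17 rose, and 18 list-wise (median log2 fold change 1.91, camera p = 9.66e-21, estimated-correlation p = 0.0732). Among them Gfap, a filament protein of reactive glia, reached 129 ± 64.3 CPM from 22.6 ± 2.23, a log2 fold change of 2.51. Cebpd, a factor of acute inflammation, rose by 2.45. Of 16 immediate early genes, 10 rose and 12 list-wise (median 0.97, camera p = 3.32e-08, estimated-correlation p = 0.0327), including Fosb by 1.55 and Atf3, a factor of the response to cell injury, by 1.93. Ecel1, a membrane peptidase, rose by 6.59 on the log2 scale to 42.5 ± 27.8 CPM. The Rag2 libraries, also at day 3 but normalised separately, held 0.167 to 1.225 CPM of it. Fgf2, a growth factor that protects photoreceptors, rose by 1.79 to 73 ± 25 CPM. The Muller glia list split, with Hes1 higher and Glul and Car14 lower, and 2 up and 4 down of 12 list-wise. Its median and mean were 0.05 while camera pointed down (adjusted p = 0.483).

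Phagocyte lists were higher at day 3 by camera, though none passed with an estimated correlation. In the monocyte and macrophage list, 16 of 22 genes rose and 19 list-wise (median 2.02, camera p = 8.14e-12, estimated-correlation p = 0.192). Fcer1g, the shared signalling chain of Fc receptors, rose by 2.24 on the log2 scale, and Spp1, the secreted matrix protein osteopontin, reached 109 ± 50.3 CPM from 24.6 ± 2.09. In the microglia list 7 of 12 rose and 10 list-wise (median 1.43, camera p = 7.7e-08, estimated-correlation p = 0.0823), with the fractalkine receptor Cx3cr1 at 1.42 and the lipid receptor Trem2 at 1.93. In the complement list 12 of 17 rose and 15 list-wise (median 1.94, camera p = 9.42e-10, estimated-correlation p = 0.192). C1qb and C1qc, subunits of the C1q starter molecule, rose by 2.19 and 2.16. In the chemokine list 7 of 12 rose and 1 fell, and 8 and 1 list-wise (median 2.01, camera p = 2.11e-05, estimated-correlation p = 0.192). Ccl2 and Ccl12, which draw monocytes, rose by 4.64 and 3.87, each from under 0.2 CPM.

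The neutrophil list was higher at day 3 by camera, a call that several alternatives ended. In it 6 of 13 genes rose and Hdc, which makes histamine, fell, with 10 up and 2 down list-wise (median 2.28, camera p = 0.00287, estimated-correlation p = 0.423). The call was also lost with fry (adjusted p = 0.0521) and with only the compared groups in the fit (camera adjusted p = 0.171). It was also lost without day 3 replicate 3, day 7 replicate 2 and day 14 replicate 1 together (median 1.65, 0.0563) and with lens and cornea scores as covariates (median 0.61, 0.0702). Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 3.41 on the log2 scale and the granule protease Prtn3 by 1.6. The calgranulin S100a8 rose by 5.62 ± 1.47 (SE), to 6.72 ± 12 CPM, with overlap between the groups. In the neutrophil recruitment list 4 of 9 rose and 9 list-wise (median 2.19, camera p = 2.11e-05, estimated-correlation p = 0.192). The 4 were C5ar1, the receptor for complement fragment C5a, at 2.55, the attractant Cxcl5 at 3.5, and the adhesion molecules Vcam1 at 1.18 and Icam1. Within groups the neutrophil score moved with the cornea and conjunctiva score over the 16 libraries (Pearson r = 0.874, permutation p = 0.00058).

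Interferon, matrix, vessel and division lists were higher by camera, and none passed with an estimated correlation. In the interferon gamma and antigen presentation list 11 of 27 rose and 23 list-wise (median 1.4, camera p = 1.18e-09, estimated-correlation p = 0.391). In the type I interferon list Mx2, Bst2, Ifit2 and Xaf1 rose of 20 genes, and 6 list-wise (median 1.47, camera p = 4.15e-06, estimated-correlation p = 0.435). In the extracellular matrix and fibrosis list 8 of 25 rose and 16 list-wise (median 1.22, camera p = 1.06e-09, estimated-correlation p = 0.307). Lox, which cross-links collagen, rose by 4.18, the macrophage elastase Mmp12 by 4.36 and the metalloproteinase inhibitor Timp1 by 3.38. Of 17 endothelial genes 1 rose, Pecam1, and 1 list-wise (median 0.92, camera p = 0.00136, estimated-correlation p = 0.435). Of 21 angiogenic factors, Fgf2 and Aplnr, the apelin receptor of growing vessels at 4.26, rose, and 2 list-wise (median 0.58, camera p = 0.00544, estimated-correlation p = 0.423). Of 11 pericyte and smooth muscle genes Actg2, Cnn1, Abcc9 and Des rose, 4 list-wise (median 0.72, camera p = 0.00949, estimated-correlation p = 0.435). In the proliferation list 12 of 20 rose and 19 list-wise (median 1.97, camera p = 2.89e-07, estimated-correlation p = 0.423), among them the mitotic kinase Aurkb at 2.95 and the cyclin Ccnb1 at 2.94. Of 12 common gamma chain receptors and signalling genes Jak3, Il4ra and Il7r rose and Stat5b fell, 5 up and 1 down list-wise (median 0.66, camera p = 0.0206, estimated-correlation p = 0.435). With lens and cornea scores as covariates the type I interferon, endothelial, angiogenic, pericyte and smooth muscle and common gamma chain lists lost their call (camera p 0.448, 0.134, 0.119, 0.944 and 0.743).

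Neuronal and pigment epithelium lists were lower at day 3 by camera, and none passed with an estimated correlation. In the retinal pigment epithelium list 6 of 16 fell, also 6 list-wise (median -0.39, camera p = 0.00626, estimated-correlation p = 0.435). Lrat and Rpe65, enzymes of the visual cycle that regenerates retinal, fell by 2.02 and 1.45 on the log2 scale, to 34.8 ± 9.6 and 81 ± 24.7 CPM from 141 ± 41.3 and 222 ± 48.2. Of 13 retinal ganglion cell genes 3 fell and 5 list-wise (median -1.11, camera p = 0.000844, estimated-correlation p = 0.435), namely Isl2, the neurofilament Nefh at -1.37 and the transcription factor Pou4f1 at -1.98. Nefh and Pou4f1 kept their call in 0 of the 8 runs that left out 1 library (edgeR adjusted p up to 0.111 and 0.12). Of 20 rod photoreceptor genes Slc24a1 and Abca4 fell, 0 list-wise (median -0.6, camera p = 0.000125, estimated-correlation p = 0.435). Of 13 cone photoreceptor genes Ccdc136 and Thrb fell and Gnb3 rose, 2 and 1 list-wise (median -0.56, camera p = 0.0216, estimated-correlation p = 0.515, and 0.0869 by camera without day 3 replicate 3). Of 14 bipolar cell genes Trpm1 fell, and 3 list-wise (median -0.53, camera p = 0.000844, estimated-correlation p = 0.435). Of 15 amacrine and horizontal cell genes Onecut1 and Slc6a9 fell, 2 list-wise (median -0.74, camera p = 0.00134, estimated-correlation p = 0.423). Glra1, a glycine receptor subunit, fell by 2.69 and the transcription factor Zbtb16 by 2.55. With lens and cornea scores as covariates, an alternative chosen after seeing the data, the rod, cone and bipolar medians were positive (0.3, 0.26 and 0.11), and the ganglion cell, pigment epithelium and amacrine and horizontal cell lists lost their call (medians -0.45, -0.33 and -0.13, camera adjusted p = 0.938, 0.0702 and 0.743).

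Tissues outside the retina and choroid also showed higher values at day 3. In the lens list 6 of 21 rose, all gamma crystallins, and 8 list-wise (median 3.48, camera p = 9.88e-09, estimated-correlation p = 0.423). Crygf was at 89.1 ± 73.8 CPM against 0.222 ± 0.118, and its reads cannot be assigned with certainty because Cryge is a near-identical copy. Of 14 cornea and conjunctiva genes the keratins Krt14, Krt13 and Krt4 rose, 8 list-wise (median 1.67, camera p = 0.000844, estimated-correlation p = 0.435), Krt14 to 1503 ± 2340 CPM. Of 14 skeletal muscle genes Myl1 and Acta1 rose, 5 list-wise (median 1.3, camera p = 0.000164, estimated-correlation p = 0.435). With lens and cornea scores as covariates it was at 0.47 and lost its call (camera adjusted p = 0.263).

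NK cell genes did not pass as a list at day 3, and neither did the other lymphocyte lists. Of 38 NK cell genes 7 passed the filter, and Ccl5, a chemokine that NK and T cells secrete, rose by 1.87 ± 0.603 (SE, edgeR adjusted p = 0.0499), with 0 list-wise. Ccl5 lost its call in 7 of the 8 runs that left out 1 library (edgeR adjusted p up to 0.189) and in 6 other alternatives, limma voom (0.077) and the covariates (0.403) among them. The NK list had a median of 0.43 (camera adjusted p = 0.286), and Eomes, a transcription factor that NK cells and some retinal ganglion cells share, was at -0.93 (edgeR adjusted p = 0.169). With no filter on low counts, where fitted values of genes near 0 counts depend on the prior count, the NK median was 1.03 and passed (camera adjusted p = 0.00508). The T cell list had a median of 0.67 (camera adjusted p = 0.188), with Cd8a higher of 7 and 2 list-wise. The B cell list had 0.45 (camera adjusted p = 0.424), with Ighm, the immunoglobulin heavy chain, higher by 1.94 and Ebf1 lower of 6, and 2 each way list-wise. The other innate lymphoid list had 1.63 (camera adjusted p = 0.0862), with Il7r higher of 7 and 2 list-wise, and the dendritic cell list 1.25 (camera adjusted p = 0.0862), with Irf8 higher of 8 and 2 list-wise. Mast cell genes were too few for a list test, since 2 of 9 reached the test, Tpsb2 at 1.95 (edgeR adjusted p = 0.0852) and Mcpt4 at 2.28 (edgeR adjusted p = 0.0877). Melanogenesis was at -0.34 (camera adjusted p = 0.0643) with Slc24a5 and Tyr lower of 12 and 2 list-wise, oligodendrocytes at 0.34 (0.423) with Cnp higher and Ermn lower of 7, and erythrocytes at 1.77 (0.312) with 0 of 6 called. Hypoxia and glycolysis had a median of -0.03, a mean of 0.1 and a camera direction of down (adjusted p = 0.424), with Kdm3a and Hk2 lower of 16, and the sex-linked list was at -0.24 (camera adjusted p = 0.207) with 0 of 4 called.

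Without control replicates 1, 2, 3 and 4 the day 3 comparison called 861, 490, 292 and 639 genes, and 31, 27, 25 and 29 of the 37 named genes that passed kept their call. Without day 3 replicates 1, 3 and 4 it called 1222, 465 and 1012, with 33, 29 and 34 kept, and with lens and cornea scores as covariates 716, with 13 kept. In the 8 runs that left out 1 library, Krt14 lost its call in 6, S100a8 and Ccnb1 in 5 and Aurkb in 4.

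**Figure D2:**
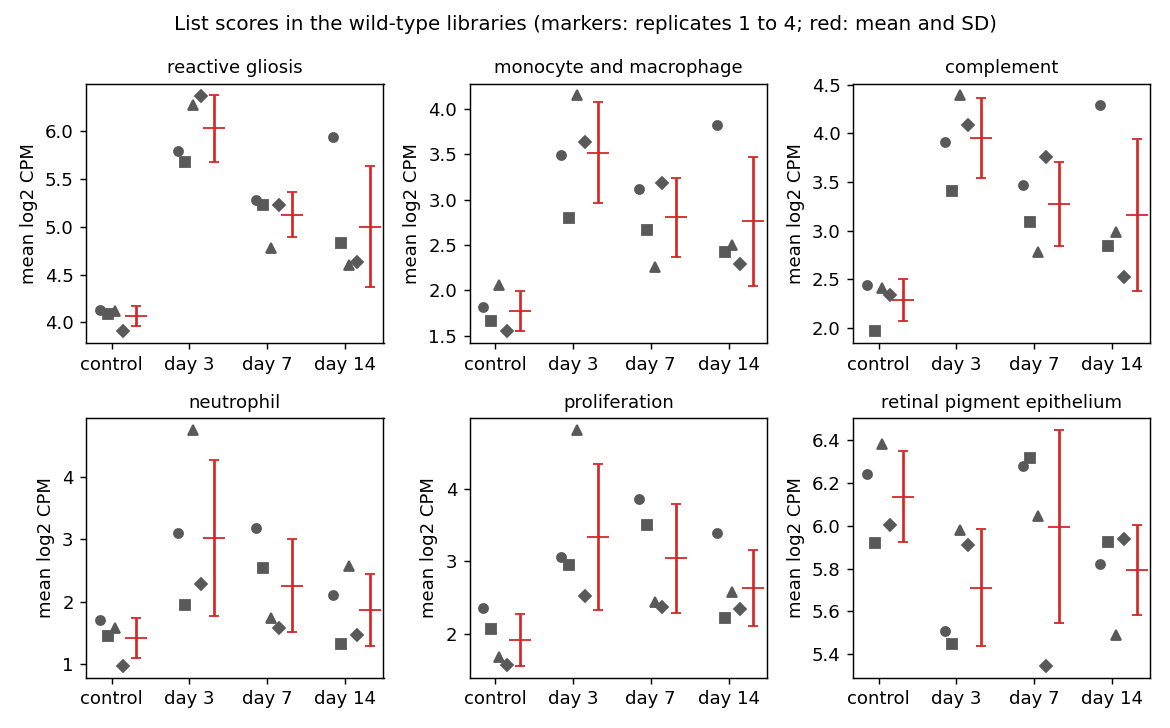
Scores of 6 gene lists (mean log2 CPM of the tested members) are drawn per wild-type library, with markers for replicates 1 to 4 and the mean and SD of each group in red (n = 4).

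At day 7 gliosis, microglia and matrix lists were higher than in control by camera, with 7 of 19, 4 of 12 and 3 of 25 genes higher by edgeR and 1 matrix gene lower. The ganglion cell, rod, bipolar cell and amacrine and horizontal cell lists were lower by camera, with 0 of 13, 0 of 20, 2 of 14 and 2 of 15 genes lower. All 18 lists called at day 7 lost their call with an estimated correlation and by exact permutation, and 3 kept it by fry. Edn2 stood at 84.4 ± 31.9 CPM (SD, n = 4), a log2 fold change of 4.07 ± 0.361 (SE, edgeR adjusted p = 2e-04), and Ecel1 rose by 6.23 on the log2 scale. Sprr1a, which epithelia and regenerating neurons express, rose by 4.88 to 28.9 ± 23 CPM. Among falls, Glra1 was lower by a log2 fold change of -3.3, Zbtb16 by -3.29, the netrin receptor Dcc by -2.88 and the potassium channel Kcnh5 by -2.71. In all, edgeR called 1962 genes, 675 higher and 1287 lower, of which 258 and 316 changed at least 2-fold. With scaling by library totals it called 1430, with 799 higher and 631 lower.

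Gliosis and phagocyte lists passed again at day 7 by camera. Of 19 reactive gliosis genes 7 rose and 12 list-wise (median 0.98, camera p = 1.59e-08, estimated-correlation p = 0.516), with Gfap at 1.5 on the log2 scale. In the microglia list Cx3cr1, Trem2, Gpr34 and Selplg rose of 12, and 8 list-wise (median 1.14, camera p = 2.26e-05, estimated-correlation p = 0.333), Cx3cr1 by 1.32 and Trem2 by 1.89. In the monocyte and macrophage list 5 of 22 rose and 9 list-wise (median 1.24, camera p = 1.45e-05, estimated-correlation p = 0.59). These were Tyrobp, Lgals3, Fcgr4, Fcer1g at 1.64 and the fungal sugar receptor Clec7a at 2.24. In the complement list C1qb, C1qc, C1qa, Itgb2 and Cfi rose of 17 and 1 fell, with 8 up and 1 down list-wise (median 1.33, camera p = 0.000128, estimated-correlation p = 0.59). The extracellular matrix and fibrosis list had Mmp12 at 3.53, Lox at 2.78 and Col3a1 higher and Tnc lower of 25, 3 and 1 list-wise (median 0.74, camera p = 0.000612, estimated-correlation p = 0.59). Of 20 proliferation genes the cyclin Ccnb2 rose by 1.87, 0 list-wise (median 1.4, camera p = 2.26e-05, estimated-correlation p = 0.59). Of 16 immediate early genes Fos, Fosb, Egr2 and the injury-responsive factor Egr1 at 1.11 rose, 8 list-wise (median 0.7, camera p = 0.000217, estimated-correlation p = 0.331). In the interferon gamma and antigen presentation list 1 of 27 was called, 0 list-wise (median 0.71, camera p = 0.00334, estimated-correlation p = 0.59).

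Neutrophil lists passed at day 7 and lost their call without single libraries. Csf3r at 2, Prtn3 at 1.64 and Asprv1 at 1.7 on the log2 scale rose of 13, and 5 list-wise (median 1.37, camera p = 0.0275, estimated-correlation p = 0.59). Asprv1 is a protease of skin that mature neutrophils also express, and it stood at 1287 ± 779 CPM with overlap between the groups. The Rag2 libraries, normalised separately and with few cornea transcripts, held 0.58 to 3.02 CPM of it, beside 1.78 to 9.32 of Csf3r. This argues against neutrophils as its main source. In the 8 runs that left out 1 library Csf3r kept its call in 0 and Asprv1 in 2 (edgeR adjusted p up to 0.118 and 0.148). Without day 7 replicate 1 the list had a median of 0.65 (camera adjusted p = 0.0865) and without control replicate 4 of 0.98 (camera adjusted p = 0.0556). Neutrophil recruitment had 0 of 9 called by edgeR, 0 list-wise (median 1.37, camera p = 0.0152, estimated-correlation p = 0.59, and 0.054 by camera without day 7 replicate 1). With lens and cornea scores as covariates the 2 medians were -0.07 and 0.62 (camera p 0.699 and 0.507).

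Retinal lists were lower and tissue lists higher at day 7 by camera, and the neuronal and muscle lists lost their call with lens and cornea scores as covariates. The medians were then 0.19 for rods, 0.15 for bipolar cells, -0.14 for amacrine and horizontal cells, -0.75 for ganglion cells and -0.09 for skeletal muscle (camera p 0.233 to 0.915). Of the 18 called lists, reactive gliosis, microglia, monocytes and macrophages, complement, immediate early genes and melanogenesis kept their call in that run. Of 13 retinal ganglion cell genes 0 were called (median -1.11, camera p = 0.00475, estimated-correlation p = 0.59). Of 14 bipolar cell genes Nyx and Trpm1, the channel of the light response in ON bipolar cells, fell, Trpm1 by 0.58 on the log2 scale, and 3 list-wise (median -0.43, camera p = 0.0105, estimated-correlation p = 0.59). Of 15 amacrine and horizontal cell genes Slc6a9 and the horizontal cell factor Onecut1 fell, Onecut1 by 3.02, 2 list-wise (median -0.56, camera p = 0.015, estimated-correlation p = 0.59). Of 20 rod genes 0 were called (median -0.36, camera p = 0.0275, estimated-correlation p = 0.674, and 0.166 and 0.102 by camera without day 7 replicates 1 and 4). Melanogenesis had Slc24a5 lower of 12, 1 list-wise (median -0.62, camera p = 0.015, estimated-correlation p = 0.59, and 0.0551 by camera without day 7 replicate 4). Among tissue lists the lens had Crygf and Cryge higher of 21, 2 list-wise (median 2.1, camera p = 0.00554, estimated-correlation p = 0.617, and 0.134 by camera without day 7 replicate 4), and Crygf overlapped between the groups. Cornea and conjunctiva had 0 of 14 called (median 1.68, camera p = 0.000358, estimated-correlation p = 0.59). Skeletal muscle had 0 of 14 called (median 0.81, camera p = 0.0233, estimated-correlation p = 0.617, and by camera 0.0621 and 0.062 without control replicates 2 and 3, 0.0979 and 0.0534 without day 7 replicates 1 and 2).

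The remaining lists did not pass at day 7, though some of their members did. The NK cell list had a median of 0.61 (camera adjusted p = 0.402) with 0 of 7 called, Ccl5 at 0.91 (edgeR adjusted p = 0.316) and S1pr5, a receptor that lets NK cells leave lymphoid tissue, at 1.18 (edgeR adjusted p = 0.202), and without control replicate 3 its median was -0.36. The T cell list had 0.23 (camera adjusted p = 0.55), the B cell list 1.11 (0.194) with Ighm higher by 1.72, and the other innate lymphoid list 0.7 (0.0707). Medians and camera p values were 0.65 and 0.245 for dendritic cells, 0.24 and 0.55 for endothelial cells, 0.06 and 0.55 for angiogenic factors and 0.83 and 0.0801 for chemokines. The vessel receptor Flt1 fell by 0.61, Aplnr rose by 2.87 and Fgf2 rose among them, though Flt1 kept its call in 1 and Aplnr in 4 of the 8 runs that left out 1 library. Among the chemokines Cxcl16 was higher and Cx3cl1 lower, and their list passed without control replicates 1, 3 or 4 or day 7 replicates 1 or 3 (camera p 0.0205, 0.0314, 0.0428, 0.0139 and 0.0276). They were 0.5 and 0.127 for type I interferon, which passed without control replicate 1 (camera adjusted p = 0.00749), 0.57 and 0.116 for common gamma chain receptors with Stat5b lower, -0.16 and 0.507 for Muller glia and -0.32 and 0.236 for cones. Retinal pigment epithelium had -0.04 and 0.507 by camera, with Slc26a7 and Lrat lower, Lrat by 1.47. Pericytes and smooth muscle had 0.38 and 0.194 by camera with Actg2 higher, and oligodendrocytes 0.32 and 0.371 with Ermn lower. Erythrocytes had 2.8 and 0.0824 by camera, with Hba-a1 and Hba-a2, near-identical haemoglobin genes whose reads cannot be told apart with certainty, higher. Hypoxia and glycolysis had -0.22 and 0.105 by camera with Kdm3a, Pfkp and the glycolytic enzyme Hk2 lower, Hk2 by 1.16. The sex-linked list had -0.34 and 0.14 by camera. Erythrocytes passed without day 7 replicates 2 or 3 (camera p 0.0219 and 0.0313), and hypoxia and glycolysis without replicate 2 (0.0417).

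Without control replicates 1, 2, 3 and 4 the day 7 comparison called 551, 425, 128 and 620 genes, and 17, 15, 8 and 20 of the 29 named genes that passed kept their call. Without day 7 replicates 1 and 2 it called 286 and 190, with 15 and 13 kept. In the 8 such runs Fcer1g, Clec7a, Hba-a2, Ccnb2 and Crygf each lost their call in 6, and Gfap and Trpm1 in 5.

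At day 14 few single genes passed, while the gliosis, phagocyte and complement lists remained higher than in control by camera, with 1 of 19 gliosis genes and 0 monocyte and macrophage, microglia or complement genes called by edgeR. None of the 22 lists called at day 14 kept its call with an estimated correlation or by exact permutation, and 2 did by fry. Edn2 stood at 45.4 ± 12 CPM (SD, n = 4), a log2 fold change of 3.17 ± 0.35 (SE, edgeR adjusted p = 0.0034). Other genes that rose included Ighm by 1.55, Ly86, a partner of a receptor on B cells and macrophages, by 1.63, the chromatin protein Hmgn3 by 1.02 and the Mediator subunit Med21 by 0.77 on the log2 scale. Among falls, the growth factor inhibitor Nog was at -2.06, the kinase phosphatase Dusp4 at -1.88, the adaptor Shc3 at -1.88 and the guanylate cyclase subunit Gucy1a2 at -2.03. Pcdhb2, a cell adhesion gene with near-identical neighbours, was at -2.14, the myelin gene regulator Myrf at -1.27, the basement membrane collagen Col8a2 at -1.22 and the microtubule protein Map1a at -1.21. In all, edgeR called 51 genes, 6 higher and 45 lower, of which 4 and 12 changed at least 2-fold, and with scaling by library totals 6, with 2 higher and 4 lower.

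Inflammatory lists passed at day 14 by camera. Edn2 was the 1 reactive gliosis gene called of 19, and 9 list-wise (median 0.91, camera p = 1.88e-08, estimated-correlation p = 0.545). Of 22 monocyte and macrophage genes 0 were called, and 13 list-wise (median 1.34, camera p = 1.12e-06, estimated-correlation p = 0.545), with Clec7a at 2.22 (edgeR adjusted p = 0.0688). Day 14 replicate 1 stood apart, with a score of 3.82 on this list beside 2.29 to 2.5. Without it the medians were 0.75 for this list, 0.59 for reactive gliosis, 0.72 for microglia and 0.53 for complement, all still called by camera, and Clec7a was at 1.29 and C1qb at 1.03. Of 12 microglia genes 0 were called and 7 list-wise (median 1.02, camera p = 2.55e-05, estimated-correlation p = 0.358), with Trem2 at 1.9 (edgeR adjusted p = 0.0559). Of 17 complement genes 0 were called, and 10 up and 1 down list-wise (median 1.28, camera p = 2.38e-05, estimated-correlation p = 0.545), with C1qb at 1.69 (edgeR adjusted p = 0.0587). Chemokines had 0 of 12, and 3 up and 1 down list-wise (median 0.97, camera p = 0.00293, estimated-correlation p = 0.545), and neutrophil recruitment 0 of 9 and 3 (median 0.73, camera p = 0.00735, estimated-correlation p = 0.545). The matrix list had 0 of 25, and 7 up and 1 down list-wise (median 0.82, camera p = 0.000475, estimated-correlation p = 0.547), with Lox at 2.29 and Mmp12 at 2.41 (edgeR adjusted p 0.0587 and 0.0688). Immediate early genes had 0 of 16 and 3 list-wise (median 0.48, camera p = 0.000475, estimated-correlation p = 0.358), with Egr1 at 1.18 (edgeR adjusted p = 0.0506). Interferon gamma and antigen presentation had 0 of 27 (median 0.63, camera p = 0.000519, estimated-correlation p = 0.547), other innate lymphoid cells 0 of 7 (1.19, 0.0301 and 0.545 in the same order) and proliferation 0 of 20 (0.92, 0.00185 and 0.561), each with 0 list-wise.

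Of the retinal and tissue lists at day 14, 0 members were called by edgeR, and 2 amacrine and horizontal cell, 5 pigment epithelium, 1 melanogenesis, 7 lens and 3 erythrocyte genes list-wise. Medians for lower lists, with camera p and estimated-correlation p, were -0.47 (0.000136 and 0.547) for rods, -0.28 (0.0481 and 0.626) for cones, -0.31 (0.00641 and 0.547) for bipolar cells and -0.44 (0.0013 and 0.545) for amacrine and horizontal cells. In the same terms they were -0.8 (0.000301 and 0.547) for ganglion cells, -0.35 (0.0103 and 0.547) for the pigment epithelium, with Lrat at -1.4 (edgeR adjusted p = 0.0669), and -0.44 (0.0345 and 0.593) for melanogenesis. Higher lists by camera were lens at 3.48 (1.49e-05 and 0.547), with Crygc at 442 ± 795 CPM against 13.8 ± 8.86, and cornea and conjunctiva at 1.12 (0.000773 and 0.547). Skeletal muscle was at 1.06 (0.00279 and 0.553) and erythrocytes at 2.44 (0.016 and 0.545). With lens and cornea scores as covariates cones were at 0.21, bipolar cells at 0.1 and proliferation at -0.22. In that run 5 of the 22 lists kept their call, reactive gliosis, monocytes and macrophages, microglia, immediate early genes and melanogenesis. By camera without day 14 replicate 1, the medians were -0.19 for rods (adjusted p = 0.107), -0.15 for amacrine and horizontal cells (0.0679) and 0.48 for skeletal muscle (0.271). Without it they were 0.22 for matrix (0.184), 0.32 for interferon gamma and antigen presentation (0.107) and 0.67 for other innate lymphoid cells (0.19), and cone and bipolar cell genes lost their call too. Ganglion cells at -0.43 (0.0206) and lens at 1.47 (0.00619) kept theirs, and Crygc was at 1.71 on the log2 scale without it and 5 with it. By camera the adjusted p for melanogenesis was 0.167, 0.248 and 0.214 without day 14 replicates 2, 3 and 4 and 0.0572 and 0.0804 without control replicates 1 and 3. For cones it was 0.0572, 0.065 and 0.056 without control replicates 1, 3 and 4, for other innate lymphoid cells 0.0714 without control replicate 4 and 0.064 without day 14 replicate 2, and for erythrocytes 0.0546 without day 14 replicate 2.

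NK cell genes did not pass at day 14, with a median of 0.66 (camera adjusted p = 0.242) and 0 of 7 called, but did with no filter on low counts (median 1.58, camera adjusted p = 0.00028). Ccl5 was at 1.6 (edgeR adjusted p = 0.138) and Itga2, an integrin on mature NK cells, at 0.72 (edgeR adjusted p = 0.212). Neutrophil genes had a median of 1.05 (camera adjusted p = 0.12), with Csf3r at 1.68 (edgeR adjusted p = 0.125) and Prtn3 at 1.27 (edgeR adjusted p = 0.0794), and 1 of 13 list-wise. By camera, T cells were at 0.35 (adjusted p = 0.389), B cells at 0.88 (0.209) and dendritic cells at 0.63 (0.312), with 2 genes higher list-wise in each of the latter lists. Type I interferon was at 0.5 (0.12) and passed without control replicate 1 (0.00366) or day 14 replicates 2 or 4 (0.0093 and 0.0156), and common gamma chain receptors were at 0.54 (0.0734) and passed without day 14 replicate 3 (0.0177). Endothelial cells were at 0.31 (0.556), angiogenic factors at 0.17 (0.775), pericytes and smooth muscle at 0.34 (0.34) and sex-linked genes at -0.1 (0.556). Muller glia had a median of -0.01 and a mean of 0.22 with camera up (0.663), oligodendrocytes a median of 0.05 and a mean of -0.01 with camera down (0.849), and hypoxia and glycolysis a median of -0.02 and a mean of 0.18 with camera down (0.47).

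Without control replicates 1, 2, 3 and 4 the day 14 comparison called 4, 3, 1 and 1 genes, and 1, 2, 1 and 1 of the 13 named genes that passed kept their call, Edn2 in each. Without day 14 replicates 1, 2, 3 and 4 it called 78, 116, 3 and 159, with 12, 11, 1 and 13 kept.

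Between the days after the laser, edgeR called 0 single genes. For day 7 against day 3, edgeR called 0 genes (1144 at an unadjusted p under 0.05), DESeq2 45, limma voom 0 and the alternatives chosen after seeing the data 3 to 15. For day 14 against day 7, edgeR called 0 (621 at an unadjusted p under 0.05), DESeq2 0 and limma voom 0. As lists, reactive gliosis (median -0.97, camera p = 4.85e-15), chemokines (-0.61, 1.9e-07), type I interferon (-1.13, 1.68e-09), monocytes and macrophages (-0.71, 1.64e-07) and endothelial genes (-0.56, 3.3e-07) were lower at day 7 than at day 3, with adjusted p of 0.173, 0.173, 0.365, 0.365 and 0.365 with an estimated correlation. From day 7 to day 14 camera found proliferation (median -0.5, adjusted p = 0.00149) and retinal pigment epithelium (-0.22, adjusted p = 0.00472) lower, each with an adjusted p = 0.984 with an estimated correlation. Between day 3 and day 7, 374 genes were higher and 879 lower than control in both, where independent calls would give 47 and 100. With the controls split so that each comparison had its own and 2 controls per fit, 1 was higher and 1 to 2 lower in both over 6 splits, while the covariance of log2 fold changes was 0.441 to 0.472, beside 0.468 with all controls.

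Groups without overlap in CPM were found for 7511 genes at day 3, 5534 at day 7 and 3642 at day 14 (40.3%, 29.7% and 19.5% of those tested), 1072 for day 7 against day 3 (5.75%) and 180 for day 14 against day 7 (0.965%), where chance gives 2.86%.

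NK receptor transcripts were few in every wild-type group. Summed over 16 NK receptor genes, as a measure added after seeing the data, the 4 libraries of each group held 14 counts in control, 68 at day 3, 36 at day 7 and 77 at day 14. Per library these were 0.227 ± 0.129, 1.04 ± 0.815, 0.578 ± 0.376 and 1.19 ± 0.786 counts-per-million (SD, n = 4). Two-sided exact permutation tests against control gave p = 0.0857, 0.0857 and 0.0286, the last being the smallest possible, and 0.3, 0.3 and 0.257 when adjusted over 18 such tests, where no single result can pass. At day 14 each library (0.664 to 2.33 counts-per-million) lay above each control (0.124 to 0.399). The 31 NK cell genes below the filter were also higher at day 14, with 4.46 ± 1.94 against 1.92 ± 0.15 (SD, n = 4, exact permutation p = 0.0286, adjusted p = 0.257). Summed counts of 6 cytotoxic effector genes were 31, 93, 39 and 90 in the same order, with 55 of the 93 in day 3 replicate 3 (exact permutation p = 0.143, 0.6 and 0.257).

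**Figure D3:**
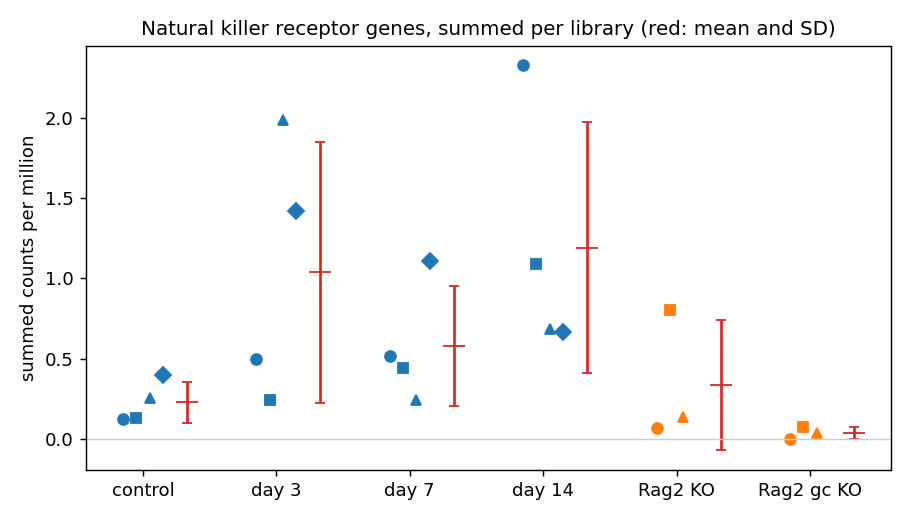
Summed counts of 16 NK receptor genes are drawn per library, in counts-per-million of all counts, with wild-type libraries in blue, Rag2 libraries in orange and the mean and SD of each group in red (n = 4 and n = 3). Rag2 KO replicate 2 held 24 of the 30 counts of its group.

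In the Rag2 pair, loss of the common gamma chain was seen in its counts. Il2rg, the common gamma chain (ENSMUSG00000031304, chromosome X, 101264378 to 101268255), had 127 counts over the Rag2 KO libraries, or 1.41 ± 0.597 CPM (SD, n = 3), and 0 over the Rag2 gc KO libraries, at least 39.1-fold lower against a floor of 3 counts over the group (edgeR adjusted p = 0.0216). By camera the microglia list was higher in Rag2 gc KO, with 2 of 12 genes called, among them Olfml3, a secreted protein of microglia, up by 1.19 on the log2 scale. The call was lost with an estimated correlation (camera adjusted p = 0.28) and by fry (0.119). NK cell and neutrophil lists did not pass. In all, edgeR called 88 genes, 40 higher in Rag2 gc KO and 48 lower, of which 16 and 19 changed at least 2-fold, with 22 of the 88 in 1 stretch of chromosome 4.

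The NK cell list had 0 of 9 measured genes called (median 0.06, camera adjusted p = 0.475), with Il2rb, the NK cell receptor subunit for interleukins, at -0.53 (edgeR adjusted p = 0.638), Il18rap at 1.91 (0.29) and Cd160 at 0.81 (0.44). NK receptor genes summed to 30 counts in Rag2 KO, 24 of them in replicate 2, and 3 in Rag2 gc KO, and effector genes to 26, 22 of them in replicate 2, and 0 (exact permutation p = 0.2 and 0.1, where 0.1 is the smallest possible). Neutrophil genes had a median of 0.15 (camera adjusted p = 0.266), with Csf3r at 1 (edgeR adjusted p = 0.34) and Cxcr2, the receptor that guides neutrophils, at 1.21 (0.288). Without Rag2 KO replicate 2 or Rag2 gc KO replicate 2 the neutrophil list passed (medians 0.61 and 0.27, camera adjusted p = 0.000332 and 0.0199), and without Rag2 gc KO replicate 3 its median was -0.01. In the neutrophil recruitment list Vcam1 rose by 0.61 on the log2 scale, 1 of 10 list-wise (median 0.58, camera p = 0.00318, estimated-correlation p = 0.542, and 0.141 by camera without Rag2 gc KO replicate 3).

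Inflammatory lists were higher in Rag2 gc KO than in Rag2 KO by camera. All 18 lists called in this pair lost their call with an estimated correlation and by fry. Of 12 microglia genes 2 rose, Olfml3 among them, and 6 list-wise (median 0.67, camera p = 1.53e-09, estimated-correlation p = 0.28), with Cx3cr1 at 0.84 (edgeR adjusted p = 0.109). Of 18 complement genes the C1 inhibitor Serping1, which lies near the Rag2 gene, rose by 0.76, a call kept in 2 of the 6 runs that left out 1 library and lost with library totals and limma voom, and 8 list-wise (median 0.7, camera p = 3.12e-10, estimated-correlation p = 0.28), with C1qb at 1.16 (edgeR adjusted p = 0.0591). Of 24 monocyte and macrophage genes 0 were called and 7 list-wise (median 0.73, camera p = 3.12e-10, estimated-correlation p = 0.542), with Spp1 at 0.98 (edgeR adjusted p = 0.113). Of 19 reactive gliosis genes 0 were called and 3 list-wise (median 1.02, camera p = 8.05e-11, estimated-correlation p = 0.542), with the adhesion receptor Cd44 at 0.89 (edgeR adjusted p = 0.0886). Matrix genes had 0 of 25 and 1 list-wise (median 0.53, camera p = 0.000189, estimated-correlation p = 0.584, and 0.406 by camera without Rag2 gc KO replicate 1). Chemokines had 0 of 14 (median 0.42, camera p = 0.0286, estimated-correlation p = 0.584, and by camera 0.0854 and 0.0626 without Rag2 KO replicates 1 and 3 and 0.631 without Rag2 gc KO replicate 1). Type I interferon had 0 of 20 (median 0.57, camera p = 0.0018, estimated-correlation p = 0.667, and by camera 0.188 without Rag2 KO replicate 3 and 0.0507 and 0.0654 without Rag2 gc KO replicates 1 and 3), with Usp18 at 1.25 (edgeR adjusted p = 0.149). Interferon gamma and antigen presentation had 0 of 26 (median 0.49, camera p = 0.000815, estimated-correlation p = 0.667, and by camera 0.0643 without Rag2 KO replicate 1 and 0.153 without Rag2 gc KO replicate 3). Proliferation had 0 of 20 and 4 list-wise (median 0.54, camera p = 7.06e-07, estimated-correlation p = 0.542).

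Retinal lists of the Rag2 pair moved by less, with 0 members called by edgeR. With camera p and estimated-correlation p, rods were at -0.2 (0.00246 and 0.643), cones at -0.37 (0.00158 and 0.542), bipolar cells at -0.11 (0.0219 and 0.542), Muller glia at 0.12 (0.0307 and 0.542) and the pigment epithelium at 0.22 (0.0286 and 0.643). In the same terms immediate early genes were at 0.25 (0.0141 and 0.584), skeletal muscle at 1.81 (6.73e-08 and 0.542), with the muscle oxygen store Mb at 2.5 (edgeR adjusted p = 0.172), and sex-linked genes at -0.14 (0.0202 and 0.584). List-wise, 1 rod gene was higher and 2 lower, 3 Muller glia genes were higher and 1 bipolar cell and 1 sex-linked gene lower. By camera, without Rag2 KO replicate 1 the adjusted p was 0.0791 for Muller glia and 0.0854 for bipolar cells, without Rag2 KO replicate 2 it was 0.127 for sex-linked genes, and without Rag2 KO replicate 3 it was 0.0634 for Muller glia and 0.454 for pigment epithelium. Without Rag2 gc KO replicate 1 it was 0.0619 for pigment epithelium and 0.0693 for sex-linked genes, and without replicate 2 it was 0.247 for Muller glia, 0.0855 for bipolar cells and 0.0555 for sex-linked genes. Without Rag2 gc KO replicate 3 it was 0.181 for rods, 0.0896 for pigment epithelium and 0.113 for immediate early genes.

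Other lists of the Rag2 pair did not pass by camera. T cells were at -0.18 (adjusted p = 0.804), B cells at -0.11 (0.795), other innate lymphoid cells at 0.07 (0.602), dendritic cells at 0.13 (0.478) and common gamma chain receptors at 0.2 (0.0902). Endothelial cells were at -0.09 (0.795), angiogenic factors at 0.14 (0.795), pericytes and smooth muscle at -0.1 (0.431), amacrine and horizontal cells at -0.14 (0.168) and ganglion cells at -0.04 (0.64). Melanogenesis was at 0.15 (0.0697), oligodendrocytes at -0.6 (0.64), lens at -0.23 (0.113), cornea and conjunctiva at 0.21 (0.795) and erythrocytes at -0.08 (0.795). Hypoxia and glycolysis had a median of -0.03 and a mean of 0.02 with camera up (0.886), Eno1 higher of 15, and 1 up and 1 down list-wise. By camera, single libraries left out gave a call for endothelial cells (0.000137), amacrine and horizontal cells (0.0456), pericytes and smooth muscle (8.13e-05) and erythrocytes (0.0138) without Rag2 KO replicate 1. They gave one for common gamma chain receptors without Rag2 KO replicate 2 (0.0198) or Rag2 gc KO replicate 1 (0.0465), and for melanogenesis without Rag2 KO replicate 2 (0.00914) or Rag2 gc KO replicate 2 (0.00986). The lens list was lower without Rag2 KO replicate 3 (0.0157) or Rag2 gc KO replicates 1 or 2 (0.0473 and 0.00154), and ganglion cells without Rag2 gc KO replicate 2 (0.0433).

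On chromosome 4, 22 called genes started between 145267137 and 156254501 (mm10), 13 higher and 9 lower in Rag2 gc KO, where 0.86 would be expected by their share of tested genes. Tnfrsf8, the receptor CD30 of activated lymphocytes, was at 8.88 ± 1.69 CPM in Rag2 gc KO and 0.0553 ± 0.0381 in Rag2 KO, a log2 fold change of 7.22 ± 0.379 (SE, edgeR adjusted p = 0.000113). The actin bundler Espn rose by 1.27, Miip by 1.22, and the zinc finger genes Zfp984 by 2.91 and Zfp933 by 1.3, while Zfp990 fell by 5.87 on the log2 scale. Reads of Zfp genes are uncertain because the family has near-identical copies. The glycolytic enzyme Eno1 rose by 0.85 while its near-identical copy Eno1b on chromosome 18 fell by 3.51, and Eno1b held 29.6% of their joint CPM in Rag2 KO, 2.01% in Rag2 gc KO and 1.8% in wild-type day 3, which was normalised separately. Outside this stretch Tecta, a matrix protein of the inner ear, fell by 5.78, the sulfotransferase Sult5a1 by 2.13 and Gm4735 by 2.16, and Gatm, an enzyme of creatine synthesis, rose by 1.52. Near the Rag2 gene on chromosome 2, 7 of 303 tested genes within 22 Mb were called (1.41 expected by their share), Serping1, Gatm and Gm4735 among them. No basis for 22 Mb was fixed in advance, so clustering there was not tested.

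**Figure D4:**
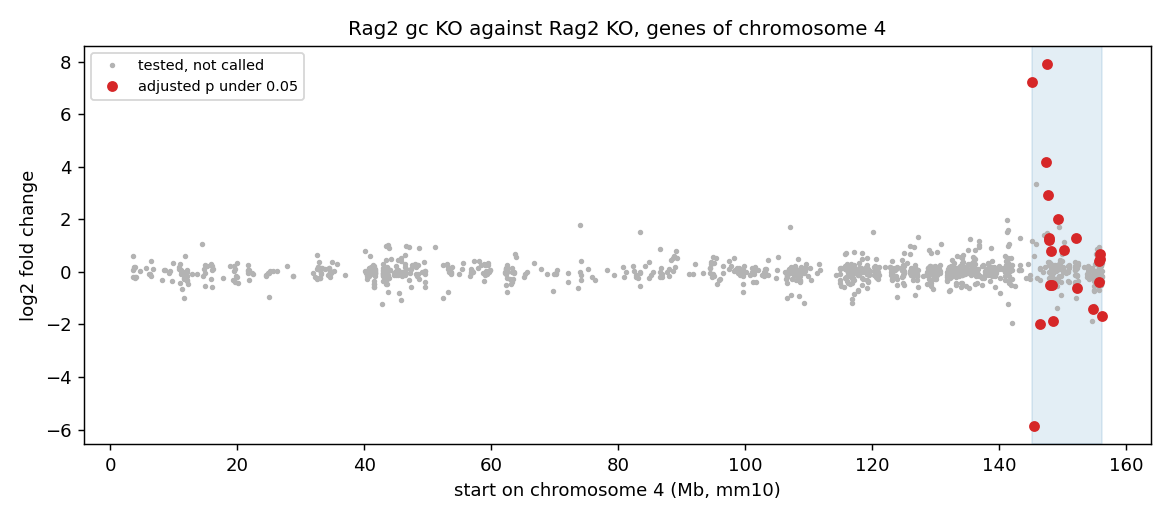
Log2 fold changes of Rag2 gc KO against Rag2 KO are drawn by start position on chromosome 4 (Mb, mm10), with called genes in red, other tested genes in grey and the window from 145267137 to 156254501 shaded.

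Groups without overlap in CPM were found for 4180 genes of the Rag2 pair (22.1%), where chance gives 10%. Without Rag2 KO replicates 1, 2 and 3 the comparison called 52, 25 and 29 genes, the adjusted p of Il2rg by edgeR was 0.0663, 0.0882 and 0.0651, and 11, 8 and 8 of the 16 named genes that passed kept their call. Without Rag2 gc KO replicates 2 and 3, 13 and 14 kept it. In the 6 such runs Sult5a1 and Eno1 lost their call in 4 and Vcam1, Gatm and Zfp984 in 3.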

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

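The tests of the 3 patterns weighed here and the splits of the samples were chosen after the results were seen. In 484 groups of 4 libraries, 37 had a highest or lowest value that stood apart from the other 3 by Dixon's test at the 95% level, 7.64% where chance gives 5% or about 24. Of these, 18 were in day 14 replicate 1, 6 in day 7 replicate 4 and 4 in day 3 replicate 3.

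Day 14 replicate 1 was high in Aplnr at 0.939 CPM (the other 3 at 0.242 to 0.293), C1qc at 52.3 (14.5 to 17.6), Clec7a at 9.46 (1.81 to 2.27), Lox at 6.43 (2.34 to 2.47), Spp1 at 78.1 (27.8 to 31.1) and Trem2 at 19.3 (5.56 to 5.92). It was low in Eomes at 0.433 CPM (4.89 to 6.04) and Hk2 at 173 (396 to 447). Its list scores in mean log2 CPM were high for monocytes and macrophages at 3.82 (2.29 to 2.5), common gamma chain receptors at 3.56 (2.59 to 2.75), reactive gliosis at 5.94 (4.6 to 4.83), melanogenesis at 5.54 (3.75 to 4.02) and pericytes and smooth muscle at 4.44 (2.91 to 3.08). They were low for rods at 8.92 (10.6 to 10.7), cones at 4.87 (6.61 to 6.62), bipolar cells at 4.81 (6.36 to 6.54) and amacrine and horizontal cells at 3.32 (5 to 5.17), and its share of rod counts was 1.57% (6.25% to 6.9%).

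Day 7 replicate 4 was high in C1qc at 37.1 CPM (22.9 to 24.2), Clec7a at 6.51 (2.85 to 3.14), Cx3cr1 at 8.59 (6.33 to 6.64) and Mmp12 at 18.7 (6.16 to 6.89), and low in Lrat at 28.7 (56.3 to 59.9) and Rpe65 at 66.6 (146 to 171). Day 3 replicate 3 was high in Sprr1a at 96.9 CPM (13.1 to 16.4) and Usp18 at 39.6 (13.9 to 15.3), low in Shc3 at 0.728 (1.96 to 2.14), and low in its rod share at 3.18% (5% to 5.32%). Day 7 replicate 3 was low in the NK cell score at 0.328 (0.998 to 1.03) and the reactive gliosis score at 4.77 (5.22 to 5.28). Day 3 replicate 2 was high in Trpm1 at 294 CPM (213 to 222). Among controls, Aplnr was high at 0.191 CPM (0.124 to 0.131) and Clec7a low at 0.699 (0.845 to 0.866) in replicate 3, Mb was high at 39.9 (10.6 to 11.4) and Usp18 at 9.77 (4.83 to 5.12) in replicate 1. Ccl12 was high at 0.195 (0.124 to 0.131) in control replicate 4 and Gfap low at 19.3 (23.6 to 24) in control replicate 2. The control flags of Aplnr and Ccl12 are 3 counts beside 2, within counting error.

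Lens and ocular surface transcripts differed between the wild-type libraries. An induction of crystallin genes in the retina is argued against, since the 6 lens fibre genes that are not crystallins had a median log2 fold change of 3.403 at day 3, beside 3.514 for 15 crystallins. Members of each list moved as 1 unit within groups, with a median pairwise correlation of 0.903 for lens and 0.868 for cornea and conjunctiva, where 95% of 1000 random lists stayed under 0.122, which is consistent with tissue carried over in the dissection. In 2 of 2 time-to-time comparisons the split of the libraries with the most calls joined the 4 highest cornea and conjunctiva shares, so this structure of the samples may also lie behind those splits. The laser cannot be excluded as a source of differences between groups, and no biological explanation within groups was tested.

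Calls of the Rag2 comparison clustered on chromosome 4, with 22 of 88 inside a 12 Mb window. Permuting the calls over all tested genes gave at most 8 in any such window in 10000 permutations (p = 1e-04, the smallest they can give), which is consistent with a linked chromosome segment that differs between the 2 strains. For 15 of the 21 genes also measured in wild-type day 3, which was normalised separately, the level there was nearer to Rag2 gc KO, and for 6 nearer to Rag2 KO. Reads shared between near-identical genes are argued against for the cluster as a whole, since zinc finger family members, pseudogenes or Eno1 made up 27.3% of it, 6 genes. An effect of the missing common gamma chain on the 22 genes cannot be told apart from strain, because the 1 contrast joins both.

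The neutrophil list was higher at day 3. A single library is argued against, since the median was 1.634 without day 3 replicate 3. Over the 16 libraries, deviations of the neutrophil score from the group means went with those of the cornea and conjunctiva score (Pearson r = 0.874, permutation p = 0.00058, Spearman rho = 0.885, p = 2e-04, and r = 0.83 without the 2 libraries farthest from the median), so ocular surface tissue may carry part of the list. For the 3 core neutrophil genes r was 0.734, and 0.65 without day 3 replicate 3. Infiltration after the laser stays open as the biological explanation and was not tested apart from this.

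Other splits of the compared libraries were run with only the compared groups in the fit. At day 3 the real split gave 7171 genes and the highest other 1, and at day 7 4485 and 8. In each, 1 of 35 splits gave as many, the smallest share possible, which argues against chance without excluding it. The splits cannot tell the laser from lens tissue. At day 14 the real split gave 1 gene and the others 0, which bears on that gene and not on the 51 called with all groups in the fit. For day 7 against day 3 and day 14 against day 7 the real splits gave 0, which 35 of 35 splits reach by necessity, so the count says nothing about chance. The highest of the others, 1505 and 2401, point to a structure of the samples. For the Rag2 pair 10 splits are too few for a share under 0.05, and the real split gave 88 and the highest other 2.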

How the results depend on the processing

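Some of these runs, such as those without 3 doubted libraries, were chosen after seeing the data. Over all alternatives, 120 single-gene results had 2117 values, of which 1726 kept their direction and their side of the threshold, 350 lost the call, 40 gained one and 1 turned direction. For 136 list results with 2448 values these numbers were 2006, 302, 55 and 85, and for the NK cell and neutrophil lists with 144 values 118, 13, 5 and 8. Of 125 values for the 6 numbers of genes changed, 64 stayed within 1.5 times, 37 were lower and 24 higher. Il2rg kept its call in 9 of 13 (edgeR adjusted p up to 0.0882), and Edn2 kept its call at day 3, day 7 and day 14 in every alternative run. Over its alternatives the adjusted p of the neutrophil list ran from 0.000144 to 0.423 at day 3, 0.0124 to 0.699 at day 7 and 0.0288 to 0.948 at day 14, and that of the NK cell list from 0.00508 to 0.938, 0.127 to 0.915 and 0.00028 to 0.948 (camera, fry or exact permutation). Where no reason stands beside a value, the cause was not tested.

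By tool, DESeq2 called 4665 genes at day 3, 3603 at day 7, 1679 at day 14, 45 for day 7 against day 3 and 693 for the Rag2 pair, and limma voom 101 at day 14. With no filter on low counts, which tests more genes, 1406, 751, 26 and 491 genes changed at day 3, day 7, day 14 and in the Rag2 pair, the NK cell median was 1.025 at day 3 (camera adjusted p = 0.00508), 1.577 at day 14 (0.00028) and -0.109 in the Rag2 pair (0.632), and neutrophils were at 1.035 at day 7 (0.0703). Rag2 B cells were at 0.026 without that filter and at 0.015 with a filter of 1 CPM. Library totals left 6 genes at day 14 and protein-coding genes only 82. A log2 fold change of at least 1 left 1162, 574, 16 and 35, and an adjusted p under 0.01 by edgeR left 124, 162, 1 and 15, at day 3, day 7, day 14 and in the Rag2 pair.

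With only the compared groups in the edgeR fit, 7171, 4485 and 1 genes changed at day 3, day 7 and day 14. Neutrophil medians were then 2.18, 1.437 and 1.08 (camera adjusted p 0.171, 0.0769 and 0.0288), and Muller glia and hypoxia and glycolysis both stood at 0.001 at day 14. With an estimated correlation the neutrophil medians of 2.276 at day 3 and 1.367 at day 7 had a camera adjusted p of 0.423 and 0.59, by fry 0.0521 and 0.148, and by the exact permutation 0.114 at day 7.

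The replicate number as a block left 2 genes at day 14 and 46 in the Rag2 pair, with Il2rg at -8.344 (edgeR adjusted p = 0.0693). Whether the numbers pair the samples is left open. Residuals of same-number wild-type libraries correlated by 0.1045 in the median (24 pairs, -0.506 to 0.479, 12 over 0.1), and other pairs by -0.0065 (72 pairs, up to 0.596). Same-number Rag2 libraries correlated by -0.058 to 0.078. Correlations this variable can neither show nor exclude a pairing.

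Without the 3 doubted libraries 4168, 3686 and 514 genes changed at day 3, day 7 and day 14 and 9 for day 7 against day 3, and 23 of 25, 16 of 18 and 15 of 22 called lists kept their call at the 3 days. Neutrophils were at 1.649 at day 3 (camera adjusted p = 0.0563) and 1.372 at day 7 (0.0722), and hypoxia and glycolysis at 0.018 at day 3. At day 14 the medians were -0.196 for endothelial cells, -0.209 for angiogenic factors, -0.039 for type I interferon, 0.08 for cones, 0.001 for bipolar cells, -0.075 for pericytes and smooth muscle and 0.001 for sex-linked genes. With day 14 replicate 1 out of the shared spread, 6188 genes changed at day 3, 4645 at day 7 and 15 for day 7 against day 3.

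With lens and cornea scores as covariates, 716 genes changed at day 3, 103 at day 14 and 3 for day 7 against day 3. The lens and cornea lists lose their change by construction. Day 3 lens scores (8.52 to 9.63) all exceeded control (1.92 to 6.03), so true laser effects can be lost too. At the 3 days 10 of 25, 6 of 18 and 5 of 22 called lists and 13 of 37, 19 of 29 and 8 of 13 named genes kept their call. Day 3 medians were -0.02 for NK cells, 0.612 for neutrophils (camera adjusted p = 0.0702), -0.029 for T cells, -0.071 for B cells, -0.176 for Muller glia, 0.299 for rods, 0.263 for cones, 0.11 for bipolar cells, -0.138 for oligodendrocytes, -0.481 for lens, -0.484 for erythrocytes and 0.127 for hypoxia and glycolysis. At day 7 they were -0.068 for neutrophils, -0.229 for T cells, -0.191 for other innate lymphoid cells, -0.087 for endothelial cells, -0.094 for angiogenic factors, -0.707 for type I interferon (camera adjusted p = 0.000915), -0.179 for interferon gamma and antigen presentation and 0.055 for Muller glia. Rods were then at 0.192, cones at 0.252, bipolar cells at 0.146 and pericytes and smooth muscle at -0.179. Lens was at -0.282, skeletal muscle at -0.093 and S1pr5 at -0.334. At day 14 they were -0.088 for NK cells, -0.105 for T cells, -0.095 for endothelial cells, -0.115 for angiogenic factors, -0.624 for type I interferon (camera adjusted p = 0.000862), 0.065 for Muller glia, 0.21 for cones and 0.098 for bipolar cells. Pericytes and smooth muscle were then at -0.065, lens at -0.072, cornea and conjunctiva at -0.042, proliferation at -0.217 and hypoxia and glycolysis at 0.03. The Rag2 lens score as a covariate gave 0.04 for B cells and 0.056 for lens.

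With each library left out in turn, the number of genes changed ranged from 292 to 2409 at day 3, 128 to 2923 at day 7, 1 to 159 at day 14, 0 to 2 for day 7 against day 3 and 25 to 116 in the Rag2 pair, where Il2rg ranged from -8.568 to -7.953. Day 3 medians that turned ranged from -0.075 to 0.121 for Muller glia and -0.095 to 0.012 for hypoxia and glycolysis. Day 7 medians ranged from -0.362 to 0.671 for NK cells, 0.654 to 1.655 for neutrophils, -0.15 to 0.505 for endothelial cells, -0.042 to 0.239 for angiogenic factors and -0.125 to 0.207 for the pigment epithelium. Day 14 medians ranged from -0.197 to 0.573 for endothelial cells, -0.21 to 0.239 for angiogenic factors, -0.039 to 1.126 for type I interferon, -0.066 to 0.078 for Muller glia, -0.354 to 0.079 for cones and -0.404 to 0.001 for bipolar cells. They ranged from -0.076 to 0.473 for pericytes and smooth muscle, -0.141 to 0.081 for oligodendrocytes and -0.122 to 0.022 for hypoxia and glycolysis. Rag2 medians ranged from -0.007 to 0.615 for neutrophils, -0.358 to 0.038 for T cells, -0.317 to 0.08 for B cells, -0.005 to 0.187 for other innate lymphoid cells, -0.215 to 0.066 for endothelial cells, -0.084 to 0.197 for angiogenic factors and -0.17 to 0.029 for ganglion cells. They ranged from -0.314 to 0.045 for pericytes and smooth muscle, -1.024 to 0.384 for oligodendrocytes, -1.006 to 0.546 for lens, -0.363 to 0.457 for cornea and conjunctiva, -0.36 to 0.106 for erythrocytes and -0.053 to 0.042 for hypoxia and glycolysis.

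Low counts kept 31 of 38 NK cell genes out of the wild-type tests and 29 out of the Rag2 tests.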

Other observations

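The tests of list scores between the days were chosen after seeing the data. Rag2 transcripts were at 0 to 1 counts per library in the Rag2 set and 0 to 4 in the wild-type set, too few to compare.

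Differences of list scores between the days were put to 72 exact permutation tests, and 0 passed (smallest p = 0.0286, adjusted p = 0.342). As 0.0286 is also the smallest possible p, a few tests at that p cannot pass after adjustment, so the 0 does not show that the days were alike.

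In the authors' deposited table, 4236 genes were higher and 3732 lower at day 3 at an adjusted p under 0.05, 2770 and 2906 at day 7, and 520 and 590 at day 14. Of the genes edgeR called, 2728, 1954 and 51 were also called there, all with the same sign.

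The covariance of log2 fold changes over 18657 genes was 0.468 for day 3 and day 7, 0.432 for day 3 and day 14 and 0.356 for day 7 and day 14, beside 0.0682, 0.0685 and 0.0683 in 20 simulations in which only the controls were shared. Both other pairs of days shared 6 genes higher than control, with 43 lower in both for day 3 and day 14 and 44 for day 7 and day 14, where independent calls would give 0.418 and 3.49, and 0.217 and 3.1. Genes are not independent replicates, so these values carry no p.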
